A study of Homo sapiens with 6 samples.

How the data were processed

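RNA of HepG2 cells, an established human liver cancer line, was profiled in 6 libraries. Per the labels, 2 libraries carried a control hairpin (shControl), 2 carried hairpin number 1 against the circular RNA circEPB41(2) (sh1), and 2 carried hairpin number 2 against it (sh2). Per the labels' protocols, total RNA was column-purified and libraries were made with a kit for messenger RNA sequencing. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

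The authors deposited 2 tables, 1 per hairpin against the same control libraries. Per the file headers, each table gives a value per gene and sample, the authors' group means, a log2 fold change, a p-value with its adjusted p-value, and gene positions. Per the submitters' processing notes, the tools were STAR 2.5 and DESeq2 and the build was hg19. The counting tool and its strand setting are not given in the sources used here. The gene positions in the deposited tables are those of GRCh38, since 8996 of the 8997 listed genes had the same start and end as in GENCODE release 29, and coordinates are given as the tables print them.

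The deposited per-sample values are a signal of read counts divided by 1 size factor per sample, called normalized counts here. In each column all values (100%) came out as whole reads within a tolerance of 0.1 once multiplied by the size factor of that column. The recovered size factors ran from 0.941 to 1.20. The 2 tables hold the same control libraries, and all 10402 compared pairs of recovered control reads were equal. The tables differ in the scale of these libraries by under 1%, and each hairpin was tested within its own table. Recovered reads summed to between 11012331 and 14054457 per library over the listed genes, which is part of a library and not its depth.

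Each deposited table lists only genes with the authors' adjusted p-value under 0.05. From adjusted p-value, rank and p-value, the authors' deposited tables rest on 18841 tested genes for sh1 and 18857 for sh2, of which 7159 (38.0%) and 7039 (37.3%) are listed. Genes outside a table have no value here. Every test below therefore ran on genes already selected as changed, and a count of calls measures how much of that selection passes a second test, not how much of the genome changed.

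Tests were fixed before the data were examined. For normalized values the test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with genes kept at a mean of at least 10 normalized counts, group as the only term, and Benjamini-Hochberg adjustment at 0.05 over the genes of the table. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The difference between the hairpins was tested in 1 fit of the 6 libraries over genes in both tables, after the control values were put on 1 scale. 28 gene lists were written from textbook knowledge before the data were examined. They were tested with camera, a competitive test here against the other listed genes, at a preset correlation of 0.01, and again with an estimated correlation and with fry, whose p asks whether the genes of a list move on balance 1 way. With 2 libraries per group an estimated correlation is imprecise, so a call lost with it does not show that the list stayed unchanged. The endothelial list had 1 tested member and was not tested as a set. Counts of list members are limma calls adjusted over all genes tested. The counts adjusted over the list alone were equal to them in all 28 lists and both comparisons, as every tested member came from the selected genes.

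Named genes followed a rule: the host gene EPB41, the 10 highest and 10 lowest fold changes per comparison with adjusted p under 0.05, replicates that did not overlap and a mean of at least 100 normalized counts in the higher group, up to 4 called members per list with the smallest p, 6 core genes of fatty acid synthesis, and the 10 genes per direction with the largest smaller change of the 2 hairpins. A gene taken for 1 hairpin may also be given for the other. Some genes that the rule takes are not reported here. Others are said to have been chosen after their values were seen.

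The fits were tested on simulated counts with 200 genes set to change, before the filter on low values. In the simulation for sh1 on 6697 genes, 92.0% of the 1.5-fold changes and 100% of the 2-fold increases were called, and 2.54% of calls were false. In that for sh2 on 6592 genes, 92.0% and 96.0% were called, and 3.52% of calls were false. Most simulated genes were unchanged, whereas the real fits hold only genes already selected as changed. These shares of false calls therefore do not carry over to the real fits.

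Alternatives were another filter on low values, 2 other pseudocounts, quantile normalization, the replicate number as a block, all 6 libraries in 1 fit, leaving out each library, a 2-fold minimum and a stricter adjusted p of 0.01. After the data were seen, count tests on the recovered reads were added, with edgeR 4.0.16 at the deposited size factors and at TMM, upper-quartile and RLE factors over the listed genes, and with DESeq2 1.42.0. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the others. TMM and RLE factors over selected genes force these genes toward balance. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.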

Results

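The 6 HepG2 libraries fell into 3 groups of 2: a control hairpin, and hairpins number 1 and 2 against circEPB41(2), a circular RNA named after the gene EPB41. How far the 2 hairpins differ in sequence is not known here. The series title ties this RNA to energy stress, lipogenesis and histone modifications, and the comparisons ask which transcripts differ once it is targeted. Between replicates, the log2 normalized counts of listed genes had a correlation across genes of 0.993 to 0.995, and replicates of each group differed by more than sampling noise (chi-square per degree of freedom 2.59 to 6.22), so each library was counted as 1 sample. Between 11012331 and 14054457 reads per library fell on listed genes, and the full depth of the libraries is not known from the tables. Fold changes below are hairpin over control from limma with their standard errors (SE), and means are normalized counts ± SD with n = 2 per group.

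EPB41, which encodes the membrane skeleton protein 4.1R (ENSG00000159023, chromosome 1, 28887091 to 29120046, plus strand, GRCh38), has no row in either table used here, so no value is given for it. A gene-level value would not separate the circular from the linear RNA, and the knockdown itself is not checked by these data. Of the related band 4.1 genes, EPB41L1 fell by 1.19 (SE 0.07) with sh1 and by 1.56 (SE 0.08) with sh2, and EPB41L5 rose by 0.66 and 0.42.

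With sh1, most tested members of the lists of fatty acid and triglyceride synthesis, lipoproteins, cholesterol synthesis, liver identity and the cell cycle fell. FASN, the fatty acid synthase, went from 26567 ± 690 in the control to 10952 ± 281, a 2.43-fold fall, and SCD, which desaturates fatty acids, from 67640 ± 1612 to 23807 ± 239. High rises included genes that the control cells expressed little: AQP3, an aquaporin that also carries glycerol, went from 8.97 ± 5.25 to 1943 ± 105. TFF1, a trefoil peptide, stood at 1.05 in the control and 323 ± 44.5 with sh1, and KISS1, which encodes kisspeptin, at 2.11 and 469 ± 24.3. WFDC3 had no read in either control library and 122 ± 18.5 with sh1. Among genes with at least 100 normalized counts in the higher group and replicates that did not overlap, the largest falls included the organic anion transporter SLCO2B1 (24.4-fold), the fatty acid hydroxylase CYP4F3 (a log2 change of -4.00), the small membrane protein gene SMLR1 (14.4-fold), the bile acid reductase AKR1D1 (-3.81) and the glyoxylate enzyme AGXT (11.3-fold). BOLA2B also ranked among the lowest, but its control libraries held 26.3 and 702 normalized counts, it has a near-identical copy that can share its reads, and its call was lost without sh1 replicate 1 (adjusted p = 0.086) or 2 (adjusted p = 0.062), so its value is uncertain.

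Of the 35 genes on the fatty acid and triglyceride synthesis list, 26 were tested with sh1, of which 19 fell and 7 rose (camera adjusted p = 0.026; adjusted p = 0.70 with an estimated correlation). The fall of SCD was 1.51 (SE 0.05, adjusted p = 2.2e-11), that of FASN 1.28 (SE 0.04) and that of GPAM, the mitochondrial glycerol-3-phosphate acyltransferase, was 5.09-fold. DGAT2, the last step of triglyceride synthesis, fell 1.90-fold, ACACA, the acetyl-CoA carboxylase, 1.75-fold, the citrate lyase ACLY 1.60-fold, and SREBF1, the transcription factor of lipogenic genes, 1.49-fold. ACSL5, which activates long-chain fatty acids, rose 2.78-fold. FASN lies on chromosome 17 (82078333 to 82098332, minus strand), SCD on chromosome 10 (100347124 to 100364834, plus strand) and SREBF1 on chromosome 17 (17810399 to 17837002, minus strand).

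**Figure D1:**
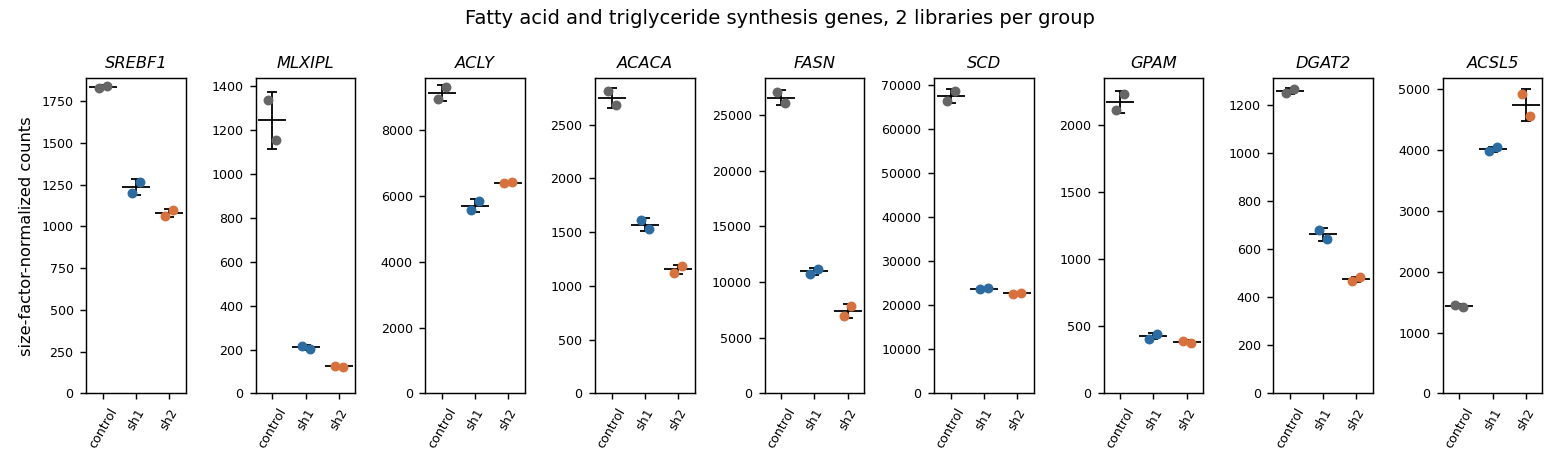
Size-factor-normalized counts (vertical axis, from 0) of 9 genes of fatty acid and triglyceride synthesis in the control, sh1 and sh2 libraries; points are single libraries, horizontal marks the means and error bars the SD of 2 libraries. Control values are those of the sh1 table. FASN stands at 26567 in the control, 10952 with sh1 and 7408 with sh2, while ACSL5 is higher with both hairpins.

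Other lipid lists also fell with sh1. On the cholesterol synthesis and uptake list 21 of 22 tested members fell (camera adjusted p = 2.8e-05), with the lanosterol synthase LSS 2.68-fold lower. All 16 tested lipoprotein and lipid export genes fell (camera adjusted p = 1.4e-05), APOB from 147855 ± 5350 to 34226 ± 1057 and APOA5 9.61-fold. On the fatty acid oxidation and ketogenesis list 18 of 20 fell (camera adjusted p = 0.0035), among them PPARGC1A, a coactivator of mitochondrial genes, by 1.84, and ANGPTL4, an inhibitor of lipoprotein lipase, rose 7.95-fold. The estimated correlation ended each of these 3 calls (adjusted p = 0.70). On the lipolysis and lipid droplet list 4 of 6 rose and 2 fell (camera adjusted p = 0.57), with a median of 0.31 and a mean of -0.08.

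Liver identity genes fell with sh1 in 23 of 26 tested cases (camera adjusted p = 2.8e-05; adjusted p = 0.70 with an estimated correlation). HNF4A, a master regulator of hepatocyte genes, fell 2.99-fold to 1283 ± 37.2, the asialoglycoprotein receptor ASGR1 by 1.95 and the fibrinogen gene FGA by 2.12. Markers of other cell types moved beside them in both directions: SOX4, expressed in progenitor cells, rose 13.9-fold, the bile duct keratin KRT19 rose 3.42-fold and SPP1 fell by 1.90 (4 rose and 2 fell on the cholangiocyte and progenitor list, camera adjusted p = 0.39, though the list passed with the replicate block). The endothelial adhesion gene ESAM rose 11.4-fold as the tested member of its list, and the actin-binding gene TAGLN rose by 3.32 while 4 other mesenchymal markers fell, PDGFRB by 2.80 (camera adjusted p = 0.53). Of 2 tested blood cell markers CD3D rose by 2.00, a call lost with quantile normalization (adjusted p = 0.10), and LYZ fell by 1.22 (camera adjusted p = 0.72, median 0.39 against a test direction of down). LYZ stood at a mean of 15260 in the control libraries, so its change need not come from blood cells.

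All 32 tested cell cycle genes fell with sh1 (camera adjusted p = 7.8e-08; adjusted p = 0.70 with an estimated correlation), MKI67, the proliferation antigen, 2.35-fold and the helicase subunit MCM4 2.80-fold. NRF2 targets fell in 17 of 18 cases (camera adjusted p = 2.8e-05; adjusted p = 0.70 with an estimated correlation), the aldo-keto reductase AKR1C1 6.16-fold and NQO1 3.27-fold. Genes of the unfolded protein response fell in 14 of 17 cases (camera adjusted p = 0.0094; adjusted p = 0.70 with an estimated correlation), including the chaperone HSPA5, 2.78-fold, and the disulfide isomerase PDIA4, 4.27-fold. The immediate early and heat shock list split into 11 that rose and 8 that fell (camera adjusted p = 0.42): the transcription factor EGR1 rose 40.5-fold and JUN 3.05-fold, whereas MYC fell by 1.00.

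Further lists did not pass camera with sh1. Among them were p53 targets with 9 rises and 7 falls (adjusted p = 0.39), in which CDKN1A, a cyclin kinase inhibitor, rose 2.95-fold, hypoxia genes with 11 rises and 6 falls (adjusted p = 0.17, but 0.039 without shControl replicate 1 and 0.031 with quantile normalization), in which adrenomedullin (ADM) rose 3.55-fold, and inflammation genes with 4 rises and 7 falls (adjusted p = 0.53), in which the chemokine CXCL8 rose 28.7-fold and CCL20 fell 5.10-fold. Histone acetylation and methylation enzymes rose in 16 and fell in 13 cases (adjusted p = 0.57), the demethylase KDM5B rising 1.80-fold and the acetyltransferase EP300 falling 1.57-fold. Energy sensing genes rose in 8 and fell in 5 cases (adjusted p = 0.31), with PRKAA2, a catalytic subunit of AMPK, up 2.02-fold and the autophagy kinase ULK1 up 2.66-fold. Gluconeogenesis genes rose in 1 and fell in 6 cases (adjusted p = 0.056), and this list passed without shControl replicate 1 (adjusted p = 0.023) or 2 (adjusted p = 0.016), with quantile normalization (adjusted p = 0.035) and without a filter on low values (adjusted p = 0.036). Bile acid genes rose in 1 and fell in 7 cases (adjusted p = 0.068), and this list passed when any 1 of the 4 libraries was left out (adjusted p = 0.032 to 0.039), with quantile normalization (adjusted p = 0.031) and without a filter on low values (adjusted p = 0.036). With the replicate block, the hypoxia, gluconeogenesis and bile acid lists also passed. Glycolysis genes rose in 5 and fell in 11 cases (adjusted p = 0.42, with the direction of the list turning to up under quantile normalization), ATF4 targets in 11 and 10 (adjusted p = 0.78), interferon genes in 8 and 5 (adjusted p = 0.57), and small RNA machinery genes in 5 and 4 (adjusted p = 0.71). Nuclear genes of oxidative phosphorylation rose in 4 and fell in 15 cases (adjusted p = 0.13), the 5 tested mitochondrially encoded genes fell (adjusted p = 0.17), with MT-ATP6 turning from -0.23 to 0.41 under quantile normalization and losing its call without sh1 replicate 2 (adjusted p = 0.053), and the 2 tested band 4.1 genes moved apart (adjusted p = 0.97).

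With sh1, the authors' deposited table lists 3516 genes that rose and 3643 that fell. All 7005 genes tested with limma passed (3390 up, 3615 down), of which 2243 changed at least 2-fold (1211 up, 1032 down). The median log2 fold change of the tested genes was -0.22, and quantile normalization moved it to -0.01, so small changes depend on the scaling.

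With sh2, FASN fell 3.61-fold, from 26706 ± 691 to 7408 ± 662, SCD 2.98-fold to 22777 ± 143, and MLXIPL, a glucose-responsive activator of lipogenic genes, 10.1-fold, from 1252 ± 129 to 123 ± 2.69. AQP3 went from 9.02 ± 5.28 to 4673 ± 390. The noncoding RNA LINC00326 went from 2.12 ± 1.49 to 593 ± 90.9, the angiotensin receptor gene AGTR1 from 1.59 ± 0.755 to 180 ± 25.7, and LINC01239 from no read in either control library to 145 ± 15.6. CDKN2B, an inhibitor of CDK4 and CDK6, rose 56.3-fold. By the same criteria, the largest falls included AKR1D1 (33.3-fold), SLCO2B1 (24.2-fold), CYP4F3 (22.4-fold), the carboxylate transporter SLC13A3 (16.8-fold) and hepcidin, HAMP (14.9-fold).

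On the fatty acid and triglyceride synthesis list 21 of 28 tested members fell with sh2 and 7 rose (camera adjusted p = 0.0092; adjusted p = 0.43 with an estimated correlation). GPAM fell 5.66-fold, DGAT2 2.66-fold, ACACA 2.40-fold, SREBF1 1.71-fold and ACLY 1.43-fold, and ACSL5 rose 3.26-fold. The cholesterol list fell in 21 of 22 cases (camera adjusted p = 2.2e-05), the squalene epoxidase SQLE 2.74-fold. All 17 tested lipoprotein genes fell (camera adjusted p = 2e-05), APOA5 13.3-fold, APOC3 12.5-fold and APOA1 4.19-fold. Fatty acid oxidation genes fell in 16 of 19 cases (camera adjusted p = 0.012), the carnitine transferase CPT1A by 1.09, and ANGPTL4 rose 15.3-fold. These 3 calls too were lost with an estimated correlation (adjusted p = 0.43). Lipolysis and lipid droplet genes rose in 4 and fell in 2 cases (camera adjusted p = 0.53), with a median of 0.52 and a mean near 0 (-0.0020).

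All 25 tested liver identity genes fell with sh2 (camera adjusted p = 3.3e-07; adjusted p = 0.43 with an estimated correlation), HNF4A 4.28-fold to 900 ± 6.69 and FGA by 2.78. Gluconeogenesis genes fell in 6 of 6 cases (camera adjusted p = 0.010) and bile acid genes in 8 of 8 (camera adjusted p = 0.012), with adjusted p = 0.43 for both with an estimated correlation. Beside them SOX4 rose 14.3-fold, KRT19 1.53-fold and ESAM 7.97-fold, while SPP1 fell by 2.28 and PDGFRB by 2.38. The cholangiocyte and progenitor list split into 2 rises and 3 falls (camera adjusted p = 0.86, median -0.48, mean 0.18) and the mesenchymal list into 4 and 4 (camera adjusted p = 0.90, median -0.06, mean 0.20). Of the blood cell markers CD3D rose by 1.58, a call lost with quantile normalization (adjusted p = 0.35) and without sh2 replicate 2 (adjusted p = 0.078), and LYZ rose by 0.21, a call lost without sh2 replicate 2 (adjusted p = 0.053) or shControl replicate 2 (adjusted p = 0.066). The list of these markers had a camera adjusted p of 0.53.

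Cell cycle genes fell with sh2 in 33 of 34 cases (camera adjusted p = 3.3e-07; adjusted p = 0.45 with an estimated correlation), MCM2 3.16-fold, and NRF2 targets in 16 of 19 (camera adjusted p = 0.0039; adjusted p = 0.53 with an estimated correlation), AKR1C1 4.41-fold. Hypoxia genes rose in 15 of 18 cases (camera adjusted p = 0.0098; adjusted p = 0.69 with an estimated correlation), ADM 2.75-fold. All 12 tested mitochondrially encoded genes fell (camera adjusted p = 0.0094; adjusted p = 0.67 with an estimated correlation), MT-ND1 2.44-fold, but the list did not pass with quantile normalization (adjusted p = 0.71), under which MT-ATP6 changed from -0.61 to 0.037. The unfolded protein response list had 4 rises and 9 falls (camera adjusted p = 0.35), the stress sensor ERN1 rising by 1.84 and PDIA4 falling 1.72-fold. EGR1 rose 33.6-fold and JUN 2.02-fold in a list of 11 rises and 8 falls (camera adjusted p = 0.41).

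The other lists did not pass camera with sh2 in the fit at the deposited scaling. Histone enzymes rose in 12 and fell in 11 cases (adjusted p = 0.90, median 0.22, mean -0.02, with fry pointing down), the methyltransferase EZH1 rising 2.80-fold and the deacetylase HDAC5 falling 2.15-fold, and energy sensing genes rose in 11 and fell in 6 (adjusted p = 0.40), PRKAA2 3.78-fold. Glycolysis genes rose in 7 and fell in 6 cases (adjusted p = 0.59), a list that passed as up with quantile normalization (adjusted p = 0.0499), with hexokinase HK1 rising 8.36-fold. The small RNA machinery rose in 6 and fell in 5 cases (adjusted p = 0.66), the argonaute AGO2 rising 2.30-fold. Counts of rises and falls were 12 and 12 for ATF4 targets (adjusted p = 0.88), 10 and 5 for p53 targets (adjusted p = 0.23), 2 and 6 for interferon genes (adjusted p = 0.39) and 1 and 3 for band 4.1 genes (adjusted p = 0.53). They were 6 and 6 for inflammation genes (adjusted p = 0.998, with a direction that turned under quantile normalization and other settings) and 6 and 11 for nuclear oxidative phosphorylation genes (adjusted p = 0.53, also turning under it).

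**Figure D2:**
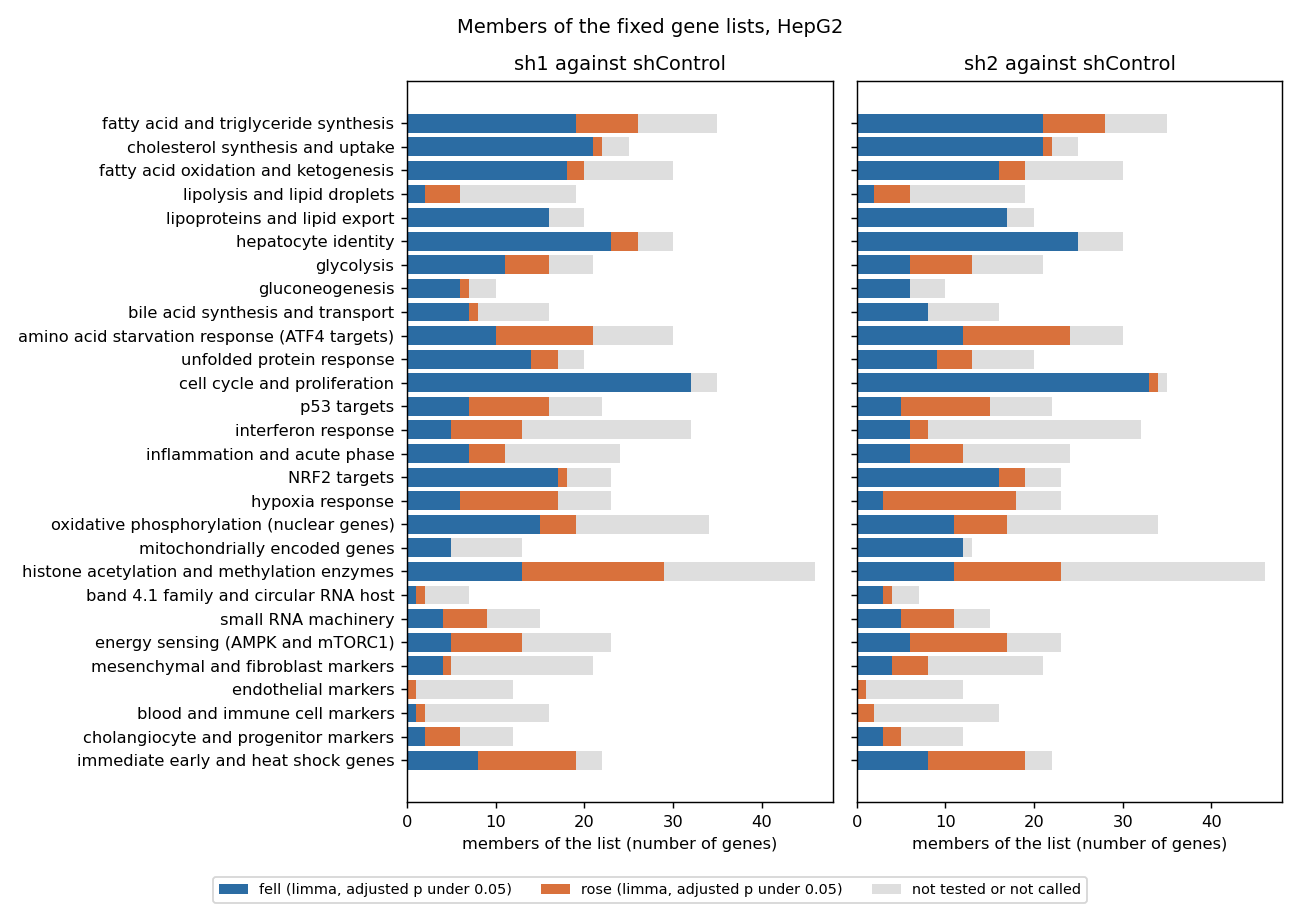
Number of genes (horizontal axis) of each of the 28 gene lists that fell (blue), rose (orange) or were not tested or not called (grey) with sh1 (left) and sh2 (right) against the control, by limma at adjusted p under 0.05 within the listed genes. All 16 and 17 tested lipoprotein genes and all 32 cell cycle genes tested with sh1 fell.

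With sh2, the authors' deposited table lists 3519 genes that rose and 3520 that fell. With limma 6884 of 6885 passed (3396 up, 3488 down), 2406 of them at least 2-fold (1188 up, 1218 down). The median log2 fold change of tested genes was -0.21, and it was 0.03 with quantile normalization.

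Both hairpins moved most shared genes the same way. AQP3, the transmembrane gene SYT11, the growth factor BMP6, VGLL3 and CDKN2B-AS1, the antisense RNA at the CDKN2B locus whose reads cannot be told from those of its partner without strand, rose with both, BMP6 by 5.20 (SE 0.29) and 5.22 (SE 0.29). SLCO2B1, CYP4F3, AKR1D1, AGXT, APOA5 and SLC13A3 fell with both. Of the 5121 genes tested in both comparisons, 5120 were called in both, 2343 up, 2638 down and 139 in opposite directions, so 97.3% shared their direction. This share covers only genes already selected with both hairpins. A further 1958 genes were listed for sh1 only and 1838 for sh2 only. The authors' deposited table of one hairpin joined with that of the other gives 2415 genes that rose and 2647 that fell in both, and 139 that moved in opposite directions. Independent lists would give 657, 681 and 1337, but these lists share their control libraries.

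**Figure D3:**
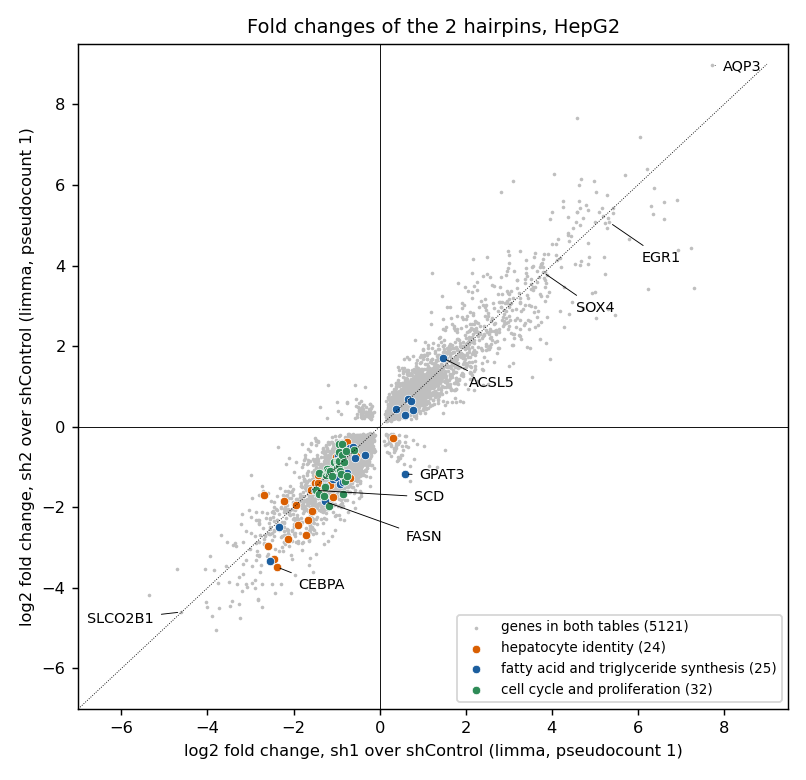
log2 fold change of 5121 genes tested in both comparisons, sh1 over shControl (horizontal) against sh2 over shControl (vertical), by limma with a pseudocount of 1; each point is a gene, colours mark 3 of the gene lists and the dotted line is equality. Of the genes called in both, 97.3% lie in the 2 quadrants of shared direction, and the gap around 0 reflects that only genes selected as changed are listed.

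Across the 5152 genes of the joint fit, which are not independent replicates, the fold changes of the hairpins had a Pearson correlation of 0.949 and a Spearman correlation of 0.941. Unchanged groups simulated against the same 2 control libraries gave a correlation of 0.503 on average, 66.7% of genes with a shared sign and, with limma in 20 draws, 0 genes called the same way in both. The covariance was 1.93 against a simulated 0.0157, a difference of 1.91. With 2 control libraries, the hairpins cannot be given separate replicated controls, so part of the excess may come from them. The selection of genes listed in both, which the simulation left out, raises the correlation and the covariance.

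The hairpins also differed from each other. Of 5152 genes 2225 differed between sh1 and sh2 (1227 higher with sh1, 998 higher with sh2), 210 of them at least 2-fold. FASN was 0.57 higher with sh1 on the log2 scale (adjusted p = 3.25e-06), ACACA 0.45 (adjusted p = 3.8e-05) and DGAT2 0.48 (adjusted p = 0.000138), that is, they fell further with sh2, as did SREBF1 (0.20, adjusted p = 0.0186). ACLY fell further with sh1 (-0.16, adjusted p = 0.0177). For SCD the difference was 0.07 (adjusted p = 0.28) and for GPAM 0.15 (adjusted p = 0.14). PDIA4 was 1.31 lower with sh1, and LYZ, lower than control with sh1 and higher with sh2, was 1.43 lower with sh1. Whether gene lists as a whole differed between the hairpins was not tested.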

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

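The tests of the shared-control noise in this part were chosen after its result was seen. The 2 hairpins, which share a target, were compared directly, and each gene named here differed between them in limma's joint fit of 6 libraries by adjusted p under 0.05 and at least 2-fold. Of the 5152 genes in that fit, all listed with both hairpins, 2225 differed between sh1 and sh2 at adjusted p under 0.05. Genes listed with 1 hairpin only were not compared. Among the named genes reported here, those higher with sh1, in log2 of sh1 over sh2, were TFF1 (3.85), KISS1 (2.81), WFDC3 (2.55), RHBG (1.46), JCAD (1.44), KRTAP3-1 (1.29), AKR1D1 (1.24), HAMP (1.17), KRT19 (1.16), DGKK (1.11) and CDKN2B-AS1 (1.07). Those lower with sh1 were LINC00326 (-3.07), ZNF804A (-3.001), GMFG (-2.98), KCNF1 (-2.21), CCL20 (-1.86), AGTR1 (-1.47), LYZ (-1.43), PDIA4 (-1.31), AQP3 (-1.26), HK1 (-1.16) and LINC01239 (-1.12). Groups hold 2 libraries each, too few for a search for single outlying samples.

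The shared direction of the hairpins was weighed against 2 technical explanations. Noise of the shared control libraries would give a covariance of the fold changes no larger than the simulated 0.0157, and the observed covariance was 1.93. The simulation left out the selection of genes listed with both hairpins, which raises the covariance, so this comparison cannot decide by itself. The control replicates themselves differed by a median of 0.0872 in log2, against an SD of the fold changes over genes of 1.39 with sh1 and 1.46 with sh2. The listed genes were selected for changes beyond replicate spread, and these 2 measures differ in kind. This second comparison therefore cannot decide either, and the replicate spread may be technical. If the control cells alone stood apart, sh1 and sh2 would differ by no more than replicates do. The SD of sh1 minus sh2 over genes was 0.461, 2.61 times the 0.177 that replicate spread gives, so the hairpins differ from each other. This bound was set beforehand but proves too weak to decide, because differences between hairpins can lie on top of a difference carried by the controls. That explanation, the targeted RNA and off-target effects of either hairpin cannot be told apart with 1 control hairpin, and the effect of the target itself stays open and untested.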

How the results depend on the processing

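The count tests on recovered reads were chosen after the data were seen. At deposited size factors edgeR called 7005 genes with sh1 and 6885 with sh2, and DESeq2 7157 and 7034. Counts of changed genes stayed within 1.5 times under every alternative except a 2-fold minimum, which left 2243 genes with sh1, 2406 with sh2 and 1503 changed the same way by both, as fewer genes pass a second condition. RLE factors over the listed genes gave the lowest counts without such a minimum or a change of gene set, 6522 and 6529. Leaving out a library gave 6817 to 7024 calls with sh1, 6609 to 6772 with sh2, 4876 to 4951 genes changed the same way by both hairpins, and 1530 to 2258 different between the hairpins. The correlation of fold changes was 0.939 to 0.955 under 2 other filters and with the deposited fold changes. Of the gene lists, 8 passed camera with sh1 and 11 with sh2. With camera at an estimated correlation 0 passed in either (smallest adjusted p = 0.70 and 0.43; 1 and 2 at an unadjusted p under 0.05), and with fry, which compares no list with other genes, 25 and 23 passed. The correlation estimated from 2 libraries per group is imprecise, and fry ran on genes already selected as changed. Neither count settles which lists moved. The cholangiocyte and progenitor list turned from down to up with fry for sh2 (median -0.48, adjusted p = 0.040), and MT-ATP6 turned from a fall to 0.41 with sh1 and 0.037 with sh2 under quantile normalization; the cause was not tested for either. Over all alternatives, values of named genes kept direction and call 4301 times, lost the call 17 times and changed sign 2 times. Samples with the same replicate number shared little deviation (correlations across genes from -0.03 to 0.08), which does not show that they were unpaired. With the replicate block, 7005 genes were called with sh1, 6878 with sh2 and 2225 between hairpins, and 4 lists passed with sh1 that had not, gluconeogenesis, bile acid, hypoxia and cholangiocyte genes. DESeq2 with its own size factors and the list tests with upper-quartile scaling were not run, and EPB41 had no value to refit. Factors over all genes could not be computed, since only listed genes have values, and for the same reason genes outside the tables cannot be called unchanged.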

Other observations

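The spread test of liver genes and the count tests with RLE factors were chosen after the data were seen. Genes that the hairpins moved in opposite directions numbered 139: 63 rose with sh1 and fell with sh2, and 76 did the reverse. Some of these changes were slight, such as -0.133 for LAMC1 with sh1. Quantile normalization moved the median of tested genes from -0.22 to -0.01 with sh1 and from -0.21 to 0.03 with sh2. The direction of slight changes, and so the count, can depend on the scaling. The genes named here were chosen after their values were seen, from those with the largest smaller change. The actin-associated gene MISP rose by 1.34 with sh1 and fell by 0.99 with sh2, the laminin chain gene LAMA3 changed by 1.14 and -0.98, and the adhesion receptor gene ADGRG1 by 0.71 and -0.99. GPAT3, a glycerol-3-phosphate acyltransferase, changed by 0.59 and -1.17, while GPAM, which catalyses the same step, fell with both. In reverse, the cytochrome CYP3A5 changed by -1.19 and 1.04, the proton pump subunit ATP6V1A by -0.75 and 0.61, and neuroplastin, NPTN, by -0.58 and 1.05. Fold changes of listed genes followed GC content more with sh2 (Spearman correlation -0.179) than with sh1 (-0.034). Its part in the opposite directions, or in other differences between the hairpins, was not tested.

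Liver genes did not fall alike, and those named here were also chosen after their values were seen. With sh2 the transcription factor CEBPA fell by 3.48 (SE 0.17), albumin (ALB) by 0.75 (SE 0.08) and AMBP, a plasma protein precursor, by 0.37 (SE 0.06). With sh1, ALB fell from 191428 ± 5343 to 94454 ± 1141, whereas CPS1 of the urea cycle rose by 0.88 and CYP2E1 by 3.54. Cells of another type without these transcripts, mixed into the hairpin cultures, would dilute all of them by 1 factor. At least 76.9% of tested members lay over 2 SE from the median of the list in each hairpin. The SE rest on 2 libraries per group, so this share is easily reached. Changes still ran from -3.48 (CEBPA) to -0.27 (FOXA1) with sh2 and from -2.675 (TTR) to 3.54 (CYP2E1) with sh1. Cells that express some of these genes themselves are not covered. A smaller share of other cells beside a change in the liver cells stays open, as mesenchymal markers moved both ways: COL3A1, with no read in the control libraries, stood at 23.9 ± 8.65 with sh2 and ACTA2, ZEB1 and CDH2 rose by 0.50, 0.52 and 0.21, while PDGFRB, COL5A1, S100A4 and FN1 fell. With sh1, TAGLN rose by 3.32 and those last 4 also fell. Scaling would need the list to come near 0 once listed genes are balanced, and its median was still -1.27 or lower with RLE factors. The range of the list argues against cells without these transcripts as the whole cause, and the RLE median against scaling as the whole cause. Loss of the targeted RNA, or a change in cell state by another route, is a candidate explanation that stays open and untested.

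Listed genes of chromosomes 16 and 22 fell more often than others. With sh1, 61.5% of 366 listed genes of chromosome 16 and 61.6% of 177 of chromosome 22 fell in the authors' deposited table (Fisher's exact test, two-sided, adjusted p = 0.00054 and 0.028 over 48 tests). With sh2 the shares were 64.9% of 328 and 65.2% of 164 (adjusted p = 1.6e-06 and 0.0012), and the genes are not independent. Other chromosomes passed too: on chromosome 6 fewer genes fell, 42.7% of 358 with sh1 (adjusted p = 0.013) and 41.4% of 365 with sh2 (adjusted p = 0.0067), as on chromosome 5 with sh2 (41.6% of 310, adjusted p = 0.017). All 17 listed mitochondrial genes fell with sh2 (adjusted p = 0.00036), although MT-ATP6 turned to 0.037 under quantile normalization. These were not tested further. GC content was set against this in a logistic model with length and level: the odds ratio of falling was 1.66 with sh1 and 1.64 with sh2, with a lower 95% bound of at least 1.34, though in sh2 it came down from 1.96 without these terms. Neighbouring genes were thinned to 1 per 500 kb, which left a lower bound of 1.135 or above, the outcome set beforehand as speaking against neighbours as the cause. The outcome set beforehand as speaking for them was an interval that includes 1 once genes with a listed neighbour of the same direction within 100 kb are dropped. That gave odds ratios of 1.04 (95% interval 0.728 to 1.49) with sh1 and 0.685 (0.476 to 0.984) with sh2, so it was met with sh1 and passed below 1 with sh2. This choice was a poor one, because where most genes fall, a gene that fell more often has such a neighbour and is dropped, which lowers the odds ratio by itself. Chromosomes 16 and 22 were picked from the 48 tests of these same data and the hairpins share their controls, so the odds ratios can overstate the pattern. With sh1 the odds ratio was 1.60 without GC content, length and level and 1.66 with them, which argues against GC content as the whole cause there. With sh2 these terms took up part of it. The 2 tests of neighbours gave different outcomes, so a few neighbours as the cause stay open. On chromosome 16, 64.4% of 208 listed genes of the short arm and 57.6% of 158 of the long arm fell with sh1. With sh2 the shares were 71.7% of 180 and 56.8% of 148, and the arms were not compared by a test. A difference in copy number between the control and hairpin cells may be worth a look, which no value here tests.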
